A study of Mus musculus with 4 samples.

How the data were processed

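Deposited tables of unique molecular identifier (UMI) counts per gene and cell were the starting point. Per the submitters' processing notes, reads were processed with Cell Ranger against mm10; the version of the program and of the gene models is not given in the sources used here. The authors deposited raw UMI counts after filtering cells and genes, per the labels, and the whole numbers in the tables are in that unit. Cut-offs of that filter, tissue dissociation, any sorting and the clustering steps are not given in the sources used here. Per the labels, each sample was a pool of 3 mice bearing subcutaneous tumours, on the 10x Genomics platform. Per the labels, the first LLC library came from mice with floxed F11r and no LysM-Cre, and the other libraries from C57BL/6J mice. Per the labels, the antibody tag sample has no table of its own and its values are linked to the CITE-seq RNA sample.

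The joint table of the LLC and B16 libraries was used for all cell classes. The table of monocytes and macrophages joined the LLC, CITE-seq LLC and B16 libraries and was used for subsets. Cell names are the authors' deposited annotation, per the labels of the cell tables, and were not redone. Another annotation, of the B16 library alone, served as an alternative. The subset names TAM-1 to TAM-4 of the monocyte and macrophage table are not the same clusters as the names TAM-1 to TAM-3 of the joint table. The 25 annotated clusters of the joint table were put into 14 classes, with all monocyte and macrophage clusters in 1 class and neutrophil-like monocytes apart. Merging monocytes with macrophages was decided after the marker check, in which the reference was also changed from all other cells to cells outside the cluster's own class. Under the first reference, monocyte markers led in Imm TAM-1 (2 markers) and Imm TAM-4 (1), a cDC1 marker in TAM-3 (1) and a plasma cell marker in Imm TAM-2 (1). The 6 columns of map coordinates in the cell tables were not used here.

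Shares are cells of a class over all cells of the library, with exact 95% Clopper-Pearson intervals. Shares were compared by their ratio with an exact conditional binomial interval. Expression is the sum of UMIs of a gene over the cells of a class, over the total UMIs of that class, on the usual CPM scale. Ratios of summed counts have exact conditional binomial 95% intervals, and single values have exact Poisson intervals. A gene was measured when it had at least 20 UMIs over both sides. Ratios against 0 UMIs are given as at least the value at a floor of 3 counts. Expression was compared between tumours in the 7 classes with at least 50 cells in both libraries. No test, p value or standard error was computed, because each group is 1 library and cells of 1 library are not replicates. A gene was called higher or lower at a 1.5-fold difference and between otherwise, which is a rule of size alone.

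Genes with no UMI in a whole library were left out of every ratio of the report with that library, since the tables look as if genes were filtered within each library before joining. That rule was set after seeing the values, and an alternative and some tests of the closing section kept those genes. Gene positions are from GENCODE vM21 on mm10, matched by gene symbol. Genes are named by a rule. In monocytes and macrophages it takes the 10 highest and 10 lowest genes, and in every other compared class the 5 highest and 5 lowest. Ranking used the bound of the 95% interval nearest to 1, among genes with at least 20 UMIs over both sides and 50 CPM in the higher. For the monocyte and macrophage table the weaker bound of the 2 LLC libraries was used. Contrasts among dendritic cell classes and among subsets took the 5 highest by the weakest bound over libraries. Mitochondrial and ribosomal protein genes, predicted genes, Rik clones, immunoglobulin and T cell receptor segments, Xist, Tsix, Y-linked and haemoglobin genes, and tumour cell genes were left out of the ranking. Cd40 was reported everywhere. Members of gene lists were named as examples by size, and any other gene was chosen after the values were seen.

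A set of 22 gene lists was written from general knowledge before the ratios were computed. It covers CD40 signalling, MHC class II presentation, MHC class I presentation, interferon response, hypoxia and glycolysis, suppressive macrophage, complement and resident-like macrophage, classical monocyte, inflammatory cytokines and chemokines, mature dendritic cell, costimulatory ligand, lipid handling, proliferation, T cell exhaustion, cytotoxicity, regulatory T cell, dissociation stress, B16 melanocytic RNA, epithelial keratin RNA of LLC, red cell RNA, platelet RNA and neutrophil RNA. For each list the median log2 ratio of measured genes was placed among 10000 random lists matched on expression in 20 bins, as a description of position. Lists with fewer than 3 measured genes have no median. Median-of-ratios scaling took off the median log2 ratio of genes with at least 20 UMIs on both sides. That median was over 0.1 from 0 in neutrophils (-0.33) and naive T cells (0.14).

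Shares of cells with a UMI were computed unthinned and after thinning each cell at random to 2000 UMIs, which leaves out cells with fewer. Antibody tags were summed per subset and expressed per 10000 antibody UMIs of that subset. A tag was read in a subset when it reached at least 3 times the highest isotype control, a rule set after seeing the values. The 3 highest such tags per subset with an RNA partner were named. No background removal or protein scaling by the authors is stated, so that step is not given in the sources used here.

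Doublets were scored with Scrublet in each library, with an expected rate of 6%. It called 1 LLC cell and 5 B16 cells in the joint table (0.00768% and 0.0728%), which is too few to count as working. Leaving out the 6% of cells with the highest scores was therefore added as an alternative. Alternatives written down before the files were seen included leaving out the cells that Scrublet called. The others were cells with at least 1000 UMIs, shares among phagocytes and dendritic cells, thinning, the mean of CPM over cells, median-of-ratios scaling, minimum counts of 1 and 100 UMIs, and totals without mitochondrial, ribosomal and stress genes. Further ones were the CITE-seq library in place of the first LLC library, equal weight per subset, centred log ratios (CLR) of tags and antibody UMIs per cell. In shares among phagocytes and dendritic cells, the phagocytes were monocytes, macrophages and neutrophil-like monocytes, without neutrophils. Alternatives added after seeing the data were the 6% doublet scores, the B16 annotation, the genes without a UMI in a library, and leaving out the 0.1% of cells with the most antibody UMIs. Equal weighting used 5 subsets with at least 20 cells in each library, a minimum set after seeing the cells per subset.

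The calculation was tested on simulated data, drawn as Poisson counts around the mean profile of both libraries with known ratios set for chosen genes. The 95% intervals held the true ratio for 95.1% of genes in monocytes and macrophages, 96.4% in cDC2 and 95.6% in the monocyte and macrophage table. With a true 2-fold difference the direction was recovered for 98.9%, 86.1% and 100% of genes. Simulated counts carry no difference between mice, so these values speak to counting error alone. Sums, cell numbers and symbols were checked against the deposited tables. The B16 table and the B16 cells of the joint table share 6772 cells, with 0 entries that differ. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9. Raw reads, spliced and unspliced counts and receptor sequences were not used here.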

Results

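Cells of subcutaneous tumours were profiled by droplet single-cell RNA sequencing in 2 mouse transplant models, the Lewis lung carcinoma line LLC and the melanoma line B16. Each tumour was 1 library from a pool of 3 mice. The joint table held 13021 LLC cells (median 6174 UMIs and 2032 genes per cell) and 6870 B16 cells (median 8315 UMIs and 2399 genes), with 13071 genes. A second LLC library was made by CITE-seq, which reads antibody tags and RNA from the same cells. For monocytes and macrophages, 8155 LLC cells, 10131 CITE-seq LLC cells and 2297 B16 cells were deposited together, with median depths of 6530, 4546 and 9250 UMIs. Antibody tags (172, of which 9 were isotype controls) were read in the CITE-seq cells at a median of 538 UMIs per cell. The first LLC library came from mice with floxed F11r and no LysM-Cre, the other libraries from C57BL/6J mice. Intervals in brackets are exact 95% intervals and cover counting error only. With 1 library per group, no difference between tumours has a replicate check, and higher or lower means at least 1.5-fold.

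Myeloid cells made up most of the LLC library, whereas lymphocytes and myeloid cells both made up large parts of the B16 library. All annotated classes of the joint table were immune cells. Shares are thus among the deposited immune cells and do not give the makeup of the tumours. T cells, NK cells, B cells and every rare dendritic cell class had a larger share in B16. Neutrophils, monocytes and macrophages had a larger share in LLC. Among conventional dendritic cells, LLC held mostly cDC2, while B16 held cDC1, cDC2 and mature migDC in similar numbers.

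Under the joint annotation, lymphocytes were 47.0% (45.8-48.2) of the B16 cells and 4.02% (3.69-4.38) of the LLC cells. Cells annotated as CD8 T cells, the cytotoxic class, were 155-fold (93.4-277) more frequent in B16, at 17.8% against 0.115%. CD8 T cells were not confined to that class, since the cells annotated naive T cells also carried Cd8b1, at 330 CPM in LLC and 448 CPM in B16, and the chemokine receptor gene Cxcr6, at 344 and 239 CPM, both chosen after their values were seen. The regulatory T cell clusters Tregs-1 and Tregs-2 were 25.2-fold (18.4-35.6) and 6.65-fold (4.79-9.41) more frequent in B16, and naive T cells 7.61-fold (6.47-8.99). NK cells, at 4.02% against 1.01%, were 3.99-fold (3.23-4.95) more frequent in B16, B cells 4.09-fold (3.22-5.22) and plasma cells 34.1-fold (11.1-171), the last from 3 LLC cells. Monocytes and macrophages were 70.6% (69.8-71.4) of LLC and 39.9% (38.8-41.1) of B16 cells, a ratio of 1.77 (1.70-1.85). Neutrophils were 15% against 4.35% (3.45-fold, 3.05-3.91), and cells annotated as neutrophil-like monocytes 6.84% against 0.451% (15.1-fold, 10.6-22.4). In LLC, 39.8% of these neutrophil-like monocytes were among the 6% of cells with the highest doublet scores, so their share may include doublets. cDC1, which cross-present antigen to CD8 T cells, were 7.26-fold (4.97-10.9) more frequent in B16, from 35 LLC and 134 B16 cells. migDC were 3.36-fold (2.57-4.41) and plasmacytoid dendritic cells (pDC) 10.3-fold (6.42-17.3) more frequent in B16. cDC2 had the same share of all cells in both tumours, 2.41% and 2.42%, but were 68.6% of the 458 LLC dendritic cells and 29.1% of the 570 in B16.

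The denominator matters here, because lymphocytes take up so much of the B16 library. A narrower base held only monocytes, macrophages, neutrophil-like monocytes and dendritic cells, without neutrophils. On it, the LLC over B16 ratio of monocytes and macrophages was 1.06 in place of 1.77. On the same base, cDC2 became lower in LLC (0.600 in place of 0.998), cDC1 0.0828 in place of 0.138 and migDC 0.179 in place of 0.298. Counting neutrophils in, which had a larger share in LLC, would lower each of these ratios further. Whether cells were sorted is not stated, and any minimum of UMIs would act first on neutrophils, which had the lowest median depth (1492 in LLC and 1700 in B16).

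**Figure D1:**
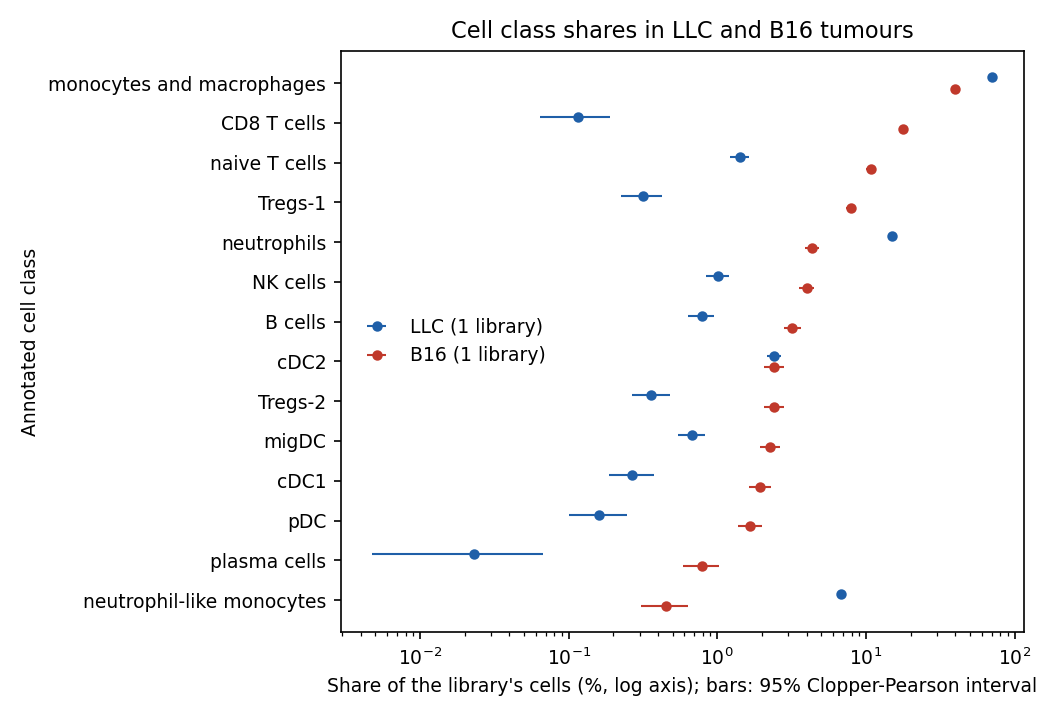
Share of all cells of the library on a log axis for each annotated class, 1 point per tumour, with exact 95% intervals as bars. CD8 T cells stand at 0.115% in LLC and 17.8% in B16, and cDC2 at 2.41% and 2.42%.

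Cd40 encodes the receptor targeted by CD40 agonists, on chromosome 2 from 165055627 to 165072948, plus strand. In both tumours its RNA was highest in migDC, at least 2-fold over any other class. LLC plasma cells, 3 cells with 0 Cd40 UMIs, are too few for that bound. cDC2 came next among dendritic cells, ahead of monocytes and macrophages. cDC1 did not exceed macrophages in either tumour. Pooled monocytes and macrophages and cDC2 carried more Cd40 RNA in B16 than in LLC, while for migDC the size of the difference varied with the way of counting.

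In migDC, Cd40 reached 200 CPM (165-241) in LLC and 246 CPM (221-272) in B16. In cDC2 it was 30.7 CPM (24.3-38.2) and 92.0 CPM (79.0-106), in cDC1 20.1 CPM (9.21-38.2) and 20.6 CPM (15.4-27.0). Monocytes and macrophages had 20.3 CPM (19.3-21.4) in LLC and 49.1 CPM (46.8-51.6) in B16, and B cells 41.3 and 58.0 CPM. Within a tumour, migDC exceeded monocytes and macrophages 9.87-fold (8.08-11.9) in LLC and 5-fold (4.45-5.61) in B16. cDC2 exceeded monocytes and macrophages 1.51-fold (1.19-1.89) and 1.87-fold (1.60-2.19). The ratio of cDC1 to monocytes and macrophages was 0.991 (0.452-1.89) in LLC and 0.419 (0.311-0.552) in B16, and the LLC value was 0.513 without the 6% of cells with the highest doublet scores. B16 over LLC, Cd40 was 2.42-fold (2.25-2.59) higher in monocytes and macrophages, 3.00-fold (2.29-3.96) in cDC2 and 1.23-fold (0.990-1.53) in migDC, the last 2.05-fold after thinning to 2000 UMIs. The mean of CPM over migDC was 207 in LLC and 233 in B16. The thinned migDC value came from a random draw over 84 LLC and 153 B16 cells and does not show an effect of depth. The macrophage value varied by cluster. In Imm TAM-3, held by 426 LLC and 637 B16 cells, Cd40 was alike at 85.1 CPM (74.9-96.3) and 79.6 CPM (72.5-87.2), whereas it was 9.04 and 28.9 CPM in Imm TAM-2 and 15.5 and 36.5 CPM in Monocytes. Depth differs between classes, so the share of cells with a Cd40 UMI was also taken at equal depth. It was 51.1% of LLC and 62.2% of B16 migDC, and 15.5% and 32.7% after thinning to 2000 UMIs. For monocytes and macrophages it was 12.8% and 33.8% (3.2% and 9.58% thinned), at median depths of 6944 and 10188 UMIs. Naive T cells, which should lack Cd40, gave 0% and 0.269% (0% and 0.147% thinned), at median depths of 2455 and 3736 UMIs. Thinning left out 133 and 39 monocytes and macrophages, 4 and 3 migDC, and 49 and 61 naive T cells of LLC and B16.

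**Figure D2:**
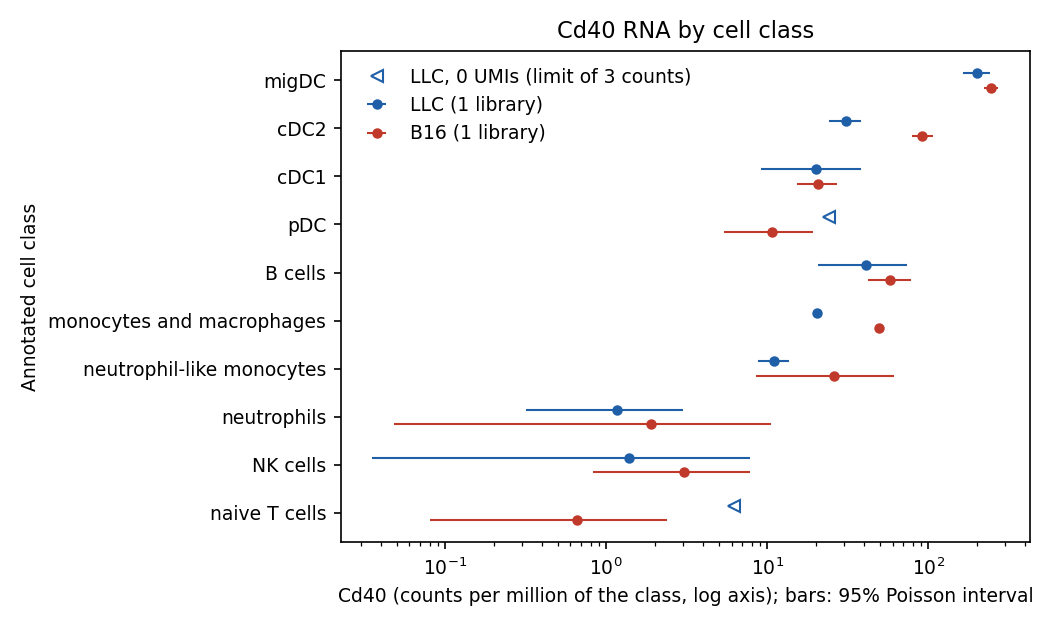
Cd40 CPM of each class on a log axis, 1 point per tumour, bars as exact 95% Poisson intervals and open triangles at the limit of 3 counts where no UMI was seen. migDC stand at 200 in LLC and 246 in B16.

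Monocytes and macrophages of the tumours differed in programme as well as in number. The B16 cells carried more RNA for interferon response, antigen presentation and cell division. Cells of the first LLC library carried more RNA of classical monocytes, whereas the median of that list in the CITE-seq LLC library lay within the 1.5-fold bound. The merged class consisted of different clusters in each tumour, which any difference in the pooled class includes. Imm TAM-4 (29.1%), TAM-1 (17.6%) and Imm TAM-1 (16.6%) were the largest in LLC, and TAM-3 (47.1%) and Imm TAM-3 (23.2%) in B16.

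Among the genes highest in LLC was Ctsk, for the collagen-degrading protease cathepsin K, at 262 CPM against 2.75 CPM (95.1-fold, 77.5-118). The gelatinase gene Mmp9 was 50.9-fold (40.4-65.0) and fibronectin Fn1 11.4-fold (11.1-11.7) higher in LLC. Other matrix and adhesion genes were Thbs1 (7.67-fold), the proteoglycan gene Vcan (6.94-fold) and podoplanin Pdpn (7.79-fold). The rest were the TGF-beta target Pmepa1 (8.92-fold), the receptor Pira2 (7.27-fold), the neutrophil attractant Cxcl2 (6.99-fold) and the platelet chemokine Ppbp (23.4-fold). Ppbp was lower in the other LLC library, at 167 CPM in LLC, 32.5 CPM in CITE-seq LLC and 7.95 CPM in B16 of the monocyte and macrophage table. Highest in B16 relative to LLC were the serpin Serpina3g (86.7-fold), the immune receptor Slamf7 (86.0-fold) and its signalling adaptor Sh2d1b1 (50.9-fold). Cxcl9, for the chemokine that draws CXCR3-bearing T cells, was at 1075 CPM in B16 and 20.5 CPM in LLC (52.5-fold). The lectin Clec4b1 (48.1-fold), the adhesion gene Vcam1 (39.9-fold) and the interferon-induced Iigp1 (32.1-fold) followed. Retnla, a mark of alternative activation, was 28.7-fold, the chemokine Ccl8 20.7-fold and AW112010 19.4-fold higher in B16. Slamf7 and Sh2d1b1 lie near F11r on chromosome 1, at the locus by which the mice differ. In the CITE-seq LLC library from C57BL/6J mice they stood at 14.8 and 15.8 CPM, against 1.66 and 1.29 CPM in the first LLC library and 147 and 72.0 CPM in B16.

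All 21 measured interferon response genes were lower in LLC (median log2 ratio -1.75, percentile 0 among random lists), with Gbp4 11-fold and Gbp2 9.31-fold higher in B16. Of the MHC class II genes, which present antigen to CD4 T cells, 9 of 11 were lower in LLC (median -1.81, percentile 0). H2-Eb1, H2-Aa and Cd74 were 5.32-fold, 4.88-fold and 3.75-fold higher in B16, and the class II regulator Ciita 3.72-fold. For MHC class I presentation 9 of 12 were lower (median -1.01), with the immunoproteasome gene Psmb9 3.65-fold and the peptide transporter Tap1 3.05-fold higher in B16. Proliferation genes were lower in LLC for 13 of 14 (median -1.16), including Ccnb2 (2.78-fold higher in B16). The cluster Prolif TAM was 3.60% of LLC and 0.292% of B16 monocytes and macrophages, but 288 cells of TAM-3 in B16 were named proliferating macrophages in the annotation of B16 alone. Lipid handling genes were split (7 lower and 3 higher in LLC of 14, median -0.48), with Lpl (18.7-fold) and Fabp4 (5.89-fold) higher in B16. Of the mature dendritic cell genes 8 of 17 were lower, among them Cd200 (8.36-fold higher in B16) and Cd83 (3.94-fold).

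Classical monocyte genes were higher in LLC for 8 of 11 (median 1.12, percentile 100), including S100a4 (3.52-fold) and F13a1 (3.24-fold). The suppressive macrophage list was split. The arginine-consuming enzyme Arg1 (4.18-fold) and osteopontin Spp1 (4.05-fold) were higher in LLC, and the PD-1 ligand Pdcd1lg2 (6.07-fold) in B16, with 6 genes higher and 5 lower of 15 (median 0.28). The complement and resident-like list was also split, 6 higher and 4 lower of 16 (median 0.24), with Cbr2 (5.19-fold), Cd163 (4.12-fold) and Folr2 (3.95-fold) higher in LLC. For the inflammatory list the median was -0.03 over 17 genes, since Cxcl3 (6.55-fold) and Cxcl1 (4.82-fold) were higher in LLC and the T cell attractants Ccl5 (6.17-fold) and Ccl4 (4.07-fold) in B16. CD40 signalling genes had a median of 0.12, with 7 of 13 between the bounds, Nfkb2 1.63-fold higher in LLC and Traf5 1.76-fold higher in B16. Costimulatory ligands had a median of 0.00 over 5 genes, with Cd80 3.88-fold higher in LLC. Hypoxia and glycolysis genes were between for 15 of 18, with Egln3 2.15-fold and Vegfa 1.87-fold higher in LLC. Dissociation stress genes were between for 10 of 16 (median 0.21), with Egr1 2.18-fold higher in LLC.

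RNA typical of other cells moved with the tumour as well. Cytotoxicity genes were lower in LLC monocytes and macrophages for all 9 (median -3.58), with Ifng 58.5-fold and Nkg7 26.8-fold higher in B16. Regulatory T cell genes were lower for 6 of 7 (median -2.65; Foxp3 18.1-fold higher in B16), T cell exhaustion genes for 3 of 6 (median -1.96; Lag3 21.9-fold). Neutrophil RNA was higher in LLC for 6 of 7 genes (median 1.52), such as Retnlg (8.23-fold) and S100a9 (2.86-fold). Red cell genes were lower in LLC for 4 of 4, with Hbb-bt 2.88-fold higher in B16. Among platelet genes only Ppbp and Pf4 (3.36-fold higher in LLC) were measured, of the keratin list only Cdh1 (5.38-fold higher in LLC), and of the melanocytic list 0 genes.

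Cells annotated Monocytes, a cluster present in both tumours, showed part of the same contrast. Of its 423 B16 cells, the annotation of B16 alone named 285 Mono-NC and 124 Mono. The LLC cells have no such annotation, so the mix of monocyte types may differ between the tumours. Their interferon response genes were lower in LLC for 18 of 20 (median -1.29; Ifit3 11.4-fold, Ifit2 8.39-fold higher in B16), and MHC class II genes for 8 of 10 (median -1.13). In LLC monocytes Cxcl3 (20.3-fold), Cxcl2 (10.8-fold), Arg1 (7.51-fold), Thbs1 (7.04-fold) and the surface protease Adam8 (6.31-fold) were highest. In B16 monocytes Sh2d1b1 (14.0-fold), Ceacam1 (6.79-fold), Fabp4 (5.83-fold), Gbp2 (4.41-fold) and Ifi211 (4.02-fold) led, and Sh2d1b1 and Ifi211 lie near F11r. Cd40 was 2.36-fold (1.76-3.16) higher in B16 monocytes. In the monocyte and macrophage table, interferon response genes of the Monocytes subset were lower for 19 of 20 in LLC but for only 9 of 20 in CITE-seq LLC (median -0.50, within the 1.5-fold bound). Proliferation genes of that subset were lower for 0 in either LLC library, and higher for 3 of 10 in LLC and 7 of 12 in CITE-seq LLC.

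In cDC2 the interferon contrast was as large as in macrophages, while MHC class II was alike in both tumours. The LLC cDC2 carried more RNA of monocytes, resident-like macrophages and neutrophils. Interferon response genes were lower in LLC for 20 of 21 (median -2.06), with Cxcl9 66.8-fold, Gbp4 14.4-fold and Gbp2 13.4-fold higher in B16. Iigp1 (82.7-fold), Il18bp (33.1-fold), which encodes an inhibitor of interleukin 18, and Slamf7 (15.2-fold) were also highest in B16. MHC class I genes were lower in LLC for 8 of 12 (median -1; Nlrc5 3.57-fold higher in B16), and MHC class II genes between for 10 of 11 (median -0.13). Complement and resident-like genes were higher in LLC for 12 of 13 (median 1.59; Folr2 15.9-fold, Trem2 6.25-fold). Classical monocyte genes were higher for 7 of 11 (median 1.34; Chil3 36.3-fold), inflammatory genes for 10 of 14 (median 1.28; Cxcl3 37.8-fold) and stress genes for 10 of 16 (median 0.65; Egr1 6.14-fold). Proliferation genes were lower for 10 of 12 (median -0.99; Ccnb2 17.2-fold higher in B16). The neutrophil genes S100a9 (67.7-fold, 40.9-121), Retnlg (156-fold, 27.8-6205, from 1 B16 UMI) and G0s2 (at least 34.5-fold), with Thbs1 (81.2-fold), were highest in LLC cDC2. All 6 measured neutrophil genes were higher (median 4.6), at a library share of neutrophils of 15% in LLC and 4.35% in B16.

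migDC of the 2 tumours were close in CD40 signalling, mature dendritic cell and MHC class II genes, and apart in interferon response and in complement and resident-like genes. All 13 CD40 signalling genes lay between the bounds (median -0.06), as did 14 of 18 mature dendritic cell genes (median 0.06) and 9 of 11 MHC class II genes (median 0.08). The chemokines Ccl17 (4.57-fold) and Ccl22 (2.56-fold), which attract CCR4-bearing T cells, were higher in LLC migDC. Interferon response genes were lower in LLC for 12 of 20 (median -0.90), with Ifit3 15.3-fold and Cxcl9 7.54-fold higher in B16. Complement and resident-like genes (8 of 11, median 1.76; C1qa 5.36-fold) and inflammatory genes (8 of 13, median 1.03) were higher in LLC. The genes highest in LLC migDC were Cxcl3 (at least 61.3-fold), Cxcl2 (81.3-fold), S100a8 (38.7-fold), S100a9 (29.8-fold) and Pf4 (23.8-fold). Those highest in B16 were Ly6a (181-fold, from 1 LLC UMI) and the T and NK cell genes Nkg7 (47.5-fold), Cd3g (37.6-fold), Il2rb (at least 11.6-fold) and Cd2 (at least 10.8-fold). Neutrophils were 15% of LLC and 4.35% of B16 cells and T cells 2.21% and 39.0%, and the source of these RNAs in migDC was not tested.

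Neutrophils, NK cells, B cells and naive T cells were compared between tumours with fewer UMIs. Neutrophils of B16 again had more interferon and MHC class I RNA, and those of LLC more hypoxia RNA. Scaling shifted neutrophil log2 ratios by -0.33, so list medians are given after that shift was taken off. Interferon response had a median of -0.65 (14 of 17 lower before the shift; Ifit3 7.78-fold higher in B16), and MHC class I presentation -0.66. Hypoxia and glycolysis had a median of 1.12 (Bnip3 3.72-fold, Ero1l 3.26-fold) and classical monocyte genes 1.87. Highest in LLC neutrophils were Chil3 (24.1-fold, 8.18-117), Lipg (24.9-fold, 6.83-206), Tgm1 (17.8-fold, 6.06-87.0), the inducible nitric oxide synthase Nos2 (13.1-fold) and F11r (22.0-fold, 7.48-107). F11r encodes junctional adhesion molecule A and is the floxed gene of the first LLC library, with 433 UMIs in LLC and 3 in B16 neutrophils. Among the highest in B16 neutrophils were Ccl8 (35.0-fold), Ccl5 (13.1-fold), Ifi204 (10.7-fold) and Ifit3. Ifi204 lies near F11r.

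Lymphocytes of LLC carried RNA typical of neutrophils and macrophages. All measured neutrophil genes were higher in LLC, with medians of 5.20 over 4 genes in NK cells, 3.51 over 5 in B cells and 1.59 over 5 in naive T cells, the last -0.041 without the 6% of cells with the highest doublet scores. In NK cells Gzmf (74.8-fold, 20.1-628), S100a8 (40.4-fold), Fn1 (40.0-fold), S100a9 (33.5-fold) and Arg1 (30.8-fold) were highest in LLC. Klrg1 (6.30-fold), a mark of mature NK cells, Ccl4 (6.50-fold), H2-Eb1 (4.89-fold), H2-Aa (4.44-fold) and the granzyme gene Gzma (3.37-fold) were highest in B16. Hypoxia and glycolysis genes were higher in LLC NK cells for 14 of 17 (median 0.84), and interferon genes were between for 12 of 20 (median 0.02). In B cells G0s2 (140-fold, 37.9-1176, from 2 B16 UMIs), Ppbp (at least 71.4-fold), Spp1 (25.2-fold), Thbs1 (23.2-fold) and Retnlg (67.5-fold) were highest in LLC. Gzma (at least 21.1-fold), Nkg7 (48.0-fold), Tnfrsf4 (16.7-fold), AW112010 (10.8-fold) and Cd3g (8.35-fold) were highest in B16 B cells. Interferon genes were lower for 10 of 13 in LLC B cells (median -1.33), and all 11 MHC class II genes were between. In naive T cells, where scaling shifted log2 ratios by 0.14, interferon response had a median of -0.11 after the shift was taken off. Ccl1 (26.8-fold), Fn1 (21.5-fold), Cxcl2 (15.9-fold), Ctse (15.3-fold) and Spp1 (12.0-fold) were highest in LLC, and H2-Aa (5.40-fold), H2-Eb1 (3.67-fold), Klra7 (3.01-fold), Cd74 (2.52-fold) and Cd7 (2.50-fold) in B16. The Ccl1 direction turned (log2 4.74 to -1.69) once those cells were left out.

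Programmes of the dendritic cell classes were then compared within each tumour. cDC1 were the dividing class, cDC2 had more classical monocyte RNA, and migDC had the mature programme with CD40 signalling. Genes that lead a class were picked to be high in both tumours and describe what was annotated. For cDC1 over the other conventional classes these were Xcr1 (181-fold in LLC and 141-fold in B16), Pclaf (80.2 and 45.8), Itgae (46.5 and 29.9), Cdk1 (45.7 and 28.2) and Tlr3 (41.8 and 27.1). Proliferation genes were higher in cDC1 for 12 of 12 in LLC and 14 of 14 in B16 (medians 2.61 and 3.26). CD40 signalling genes were lower in cDC1 for 11 of 13 and 12 of 13 (medians -1.26 and -1.62), and in cDC2 for 10 of 13 and 4 of 13 (medians -0.90 and -0.55). cDC2 were led by Cd209a (145 and 35.3), Ltb4r1 (11 and 12.4), Clec10a (10.6 and 8.59), Ly6a (9.17 and 6.44) and Mgl2 (8.67 and 7.93). Classical monocyte genes were higher in cDC2 for 8 of 11 and 8 of 10 (medians 1.13 and 1.60), and MHC class II genes for 7 of 11 and 4 of 11. Dissociation stress genes were also higher in cDC2, for 14 of 16 and 9 of 16 (medians 1.33 and 0.68). Hypoxia and glycolysis genes were higher for 13 of 17 and 8 of 17. Interferon response genes were lower in cDC1 for 11 of 20 in LLC and 17 of 21 in B16 (median -1.39 in B16). In cDC2 of B16 16 of 21 were higher (median 1.46; Ifit3 7.13-fold, Cxcl10 5.28-fold), at a median of -0.09 in cDC2 of LLC.

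migDC over the other conventional classes were led by the actin-bundling gene Fscn1 (226 in LLC and 598 in B16) and by Il12b, which encodes a subunit of interleukin 12 (1196 and 253). Ccl5 (254 and 78.4), Slc27a3 (191 and 242) and Apol7c (at least 188 and 101) followed. The LLC value of Il12b rests on 1 UMI in the other cells (213-47466). Mature dendritic cell genes were higher for 16 of 18 and 17 of 18 (medians 3.50 and 4.50). CD40 signalling genes were higher for 13 of 13 and 12 of 13 (medians 1.38 and 1.85), such as Relb (8.62 and 9.24) and Traf1 (5.12 and 7.27), transducers of the NF-kappaB pathway, beside Cd40 itself (6.89 and 4.76). Costimulatory ligands had medians of 0.36 and 2.77, with Cd80 at 3.11 and 12.2 and Cd83 at 10.8 and 6.83. Regulatory T cell genes were also higher in migDC, for 3 of 4 and 6 of 6 (medians 3.471 and 1.655). Cytotoxicity genes were higher for 5 of 7 and lower for 2 in B16. The source of this RNA was not tested. MHC class II RNA was lower in migDC for 10 of 11 genes in both tumours (medians -1.16 and -1.78), with Ciita at ratios of 0.138 and 0.146.

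Many subsets of monocytes and macrophages were held mostly by 1 tumour. TAM-1 and Immature TAM-1 of this annotation were mostly B16 cells, and TAM-2, TAM-3, TAM-4 and Immature TAM-2 were mostly LLC cells of both LLC libraries. Monocytes, Mono/TAM IFN and Mono/TAM Hypoxic were common in all libraries. A subset held by 1 library can be a difference of that library or of its tumour. TAM-1 was 41.0% of the B16 cells, against 0.0245% in LLC and 0.0395% in CITE-seq LLC. Immature TAM-1 was 22.6%, 0.307% and 0.750% in the same order. TAM-4 was 19.4% of LLC and 25.7% of CITE-seq LLC against 0.0871% of B16, TAM-3 16.6%, 22.9% and 0.740%, and TAM-2 14.0%, 8.47% and 0.261%. Immature TAM-2 was 14.2%, 9.91% and 0.958%, Immature TAM-3 2%, 4.84% and 0.305%, and LLC TAM Hypoxic 5.58%, 5.04% and 0.740%. Monocytes were 9.05%, 8.24% and 17.2%, Mono/TAM IFN 5.36%, 8.47% and 6.88%, and Mono/TAM Hypoxic 13.4%, 5.63% and 9.27%.

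Both LLC libraries were compared with the same B16 library, so the values for each are not independent. Of 908 genes at least 2-fold apart from B16 in LLC, 610 were also 2-fold apart in the same direction in CITE-seq LLC and 12 had the opposite direction, a tally that the shared B16 library raises. The genes named here were picked to be apart with both LLC libraries. Interferon, antigen presentation and proliferation RNA was again higher in B16. Higher in LLC (CITE-seq LLC in brackets) were Fcna 27.2-fold (30.1), Ltc4s 22.0-fold (24.7), Cbr2 17.0-fold (12.9), Lyz1 16.3-fold (10.6) and Fn1 10.4-fold (8.14). Pmepa1 8.14-fold (10.9), the folate receptor gene Folr2 7.90-fold (8.06), Pdpn 6.52-fold (5.11), Ecm1 5.41-fold (4.35) and Plec 4.38-fold (4.22) followed. Higher in B16 were Slamf7 88.3-fold (9.97), Serpina3g 73.3-fold (28.0), Vcam1 48.4-fold (25.1), Cxcl9 47.2-fold (20.5) and Clec4b1 45.8-fold (22.4). Ccl8 40.6-fold (36.5), Lpl 40.1-fold (19.4), Iigp1 25.1-fold (19.0), Il18bp 20.4-fold (14.3) and AW112010 18.2-fold (12.0) completed the set. Cd40 was at 21.1 CPM in LLC, 26.4 CPM in CITE-seq LLC and 50.8 CPM in B16.

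Interferon response genes were lower for 21 of 21 with LLC and 18 of 21 with CITE-seq LLC (medians -1.70 and -1.20). MHC class II genes were lower for 8 of 11 and 7 of 11 (medians -1.83 and -1.01), with H2-Eb1 5.31-fold and 3.31-fold higher in B16. MHC class I genes were lower for 9 of 12 and 11 of 12 (medians -0.98 and -1.03), and proliferation genes for 13 of 14 with either (medians -2.06 and -1.69; Mki67 5.40-fold and 3.66-fold higher in B16). No subset of this table is named proliferating, whereas the joint table holds Prolif TAM, with 331 LLC and 8 B16 cells, and gave a proliferation median of -1.16. The larger proliferation contrast may therefore depend on which cells were put into this table. Among other lists, medians with LLC and CITE-seq LLC were 1.02 and 0.18 for classical monocyte genes, 0.29 and -0.44 for suppressive macrophage genes and -0.28 and -4.84 for red cell RNA. Of the suppressive macrophage genes, Arg1 (4.01-fold and 2.26-fold) and Spp1 (3.51-fold and 2.94-fold) were higher in LLC, while the PD-1 ligand genes Pdcd1lg2 (6.38-fold and 3.90-fold) and Cd274 (2.74-fold and 3.33-fold) were higher in B16. The interferon and MHC class II contrasts were smaller with equal weight for each of 5 shared subsets. In LLC over B16, the interferon median was then -0.45, within the 1.5-fold bound, in place of -1.70. The MHC class II median was -0.74 in place of -1.83, and Cxcl9 turned from a log2 ratio of -5.56 to 0.84. The turn came from Immature TAM-1, in which Cxcl9 was 2801 CPM in 25 LLC cells and 1048 CPM in B16, whereas in Mono/TAM IFN it was 135 and 434 CPM. Equal weighting left out TAM-1 to TAM-4, Immature TAM-3 and LLC TAM Hypoxic. It weighted 25 LLC cells of Immature TAM-1 and 22 B16 cells of Immature TAM-2 as much as larger subsets. It thus cannot tell the makeup of subsets from the choice of subsets kept.

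**Figure D3:**
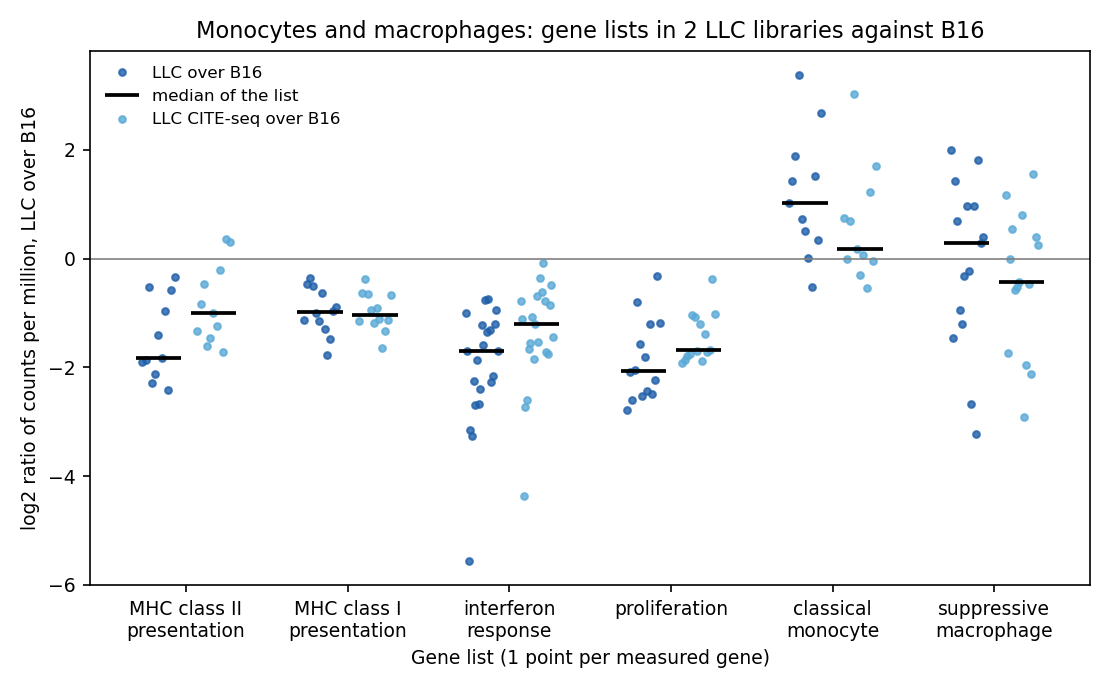
log2 ratio of CPM in all monocytes and macrophages, LLC over B16 and CITE-seq LLC over B16, 1 point per measured gene of 6 lists with the list median as a line. The interferon response medians are -1.70 and -1.20.

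Within libraries, the genes that lead a subset describe what was annotated, and some programmes led more than 1 subset. TAM-4 were resident-like macrophages, TAM-3 and Immature TAM-1 were rich in MHC class II, and the hypoxic subsets carried more hypoxia and glycolysis RNA. Values are given for LLC and CITE-seq LLC, then B16 where it held enough cells. TAM-4 were led by Gas6 (21.3 and 8.66), a ligand for uptake of dying cells, with Cbr2 (18.1 and 12.3) and Ch25h (14.8 and 6.75), and complement and resident-like genes had medians of 1.96 and 1.39. TAM-3 were led by H2-Eb1 (7.22 and 3.36), H2-Aa (6.08 and 3.17) and H2-Ab1 (5.86 and 3.24), and TAM-2 by Ccl24 (5.58 and 4.96) and Spp1 (2.49 and 3.37). TAM-1 of B16 were led by Ccl8 (33.7), Vcam1 (32.3) and Cadm1 (20.7), with a proliferation median of 2.52. Mono/TAM IFN were led by Ifit1bl1 (362, 91.7 and 89.5) and Rsad2 (120, 53.3 and 14.6), with interferon medians of 4.15, 3.75 and 2.52. Mono/TAM Hypoxic were led by the activin gene Inhba (43.7, 27.4 and 57.9), Cxcl3 (20.3, 21.0 and 73.3) and Hilpda (9.37, 8.66 and 9.02), with hypoxia medians of 1.19, 1.09 and 1.03. LLC TAM Hypoxic were led by Gdf15 (13.2 and 11.4), Mmp12 (7.72 and 5.88) and haem oxygenase Hmox1 (7 and 6.81), with hypoxia medians of 0.66 and 0.74. Monocytes were led by Ear2 (20.8, 18.0 and 18.0) and Adgre4 (17.6, 14.3 and 48.6), with classical monocyte medians of 1.94, 2.41 and 2.38. Immature TAM-2 also had high classical monocyte medians (1.54, 1.72 and 1.8), and Immature TAM-3 were led by Chil3 (2.20 and 1.92) and Plac8 (2.07 and 1.89). Immature TAM-1 had MHC class II medians of 1.88, 1.55 and 0.96.

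Cd40 RNA also differed among these subsets. It was high in Immature TAM-1 (94.4, 121 and 60.9 CPM) and Mono/TAM IFN (88.6, 85.9 and 125 CPM). TAM-1 of B16 held 46.7 CPM and TAM-4 31.6 and 30.2 CPM, whereas Mono/TAM Hypoxic held 3.98, 3.81 and 22.8 CPM and TAM-2 6.72 and 4.67 CPM.

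Surface protein was read in the CITE-seq LLC cells only, as the share of antibody UMIs in a subset over all other subsets. Protein and RNA pointed to the same subsets for resident-like, MHC class II and monocyte marks. In 107 pairs of subset and tag the protein interval lay at least 1.5-fold from no difference and the RNA was measured. Of these, 97 had the same direction in protein and RNA, whatever the size of the RNA difference. TAM-4 were highest for folate receptor beta (FRB; 5.80-fold, 5.71-5.90, with Folr2 RNA 5.96-fold), the scavenger receptor CD163 (4.49-fold; RNA 10.8-fold) and the mannose receptor CD206 (3.65-fold; Mrc1 2.56-fold). TAM-3 were high for the MHC class II tag IA-IE (2.14-fold, 2.12-2.15; H2-Ab1 3.24-fold) and CD11c (2.03-fold; Itgax 1.63-fold). Immature TAM-1 had IA-IE at 2.99-fold and the PD-L1 tag CD274 at 2.01-fold (RNA 4.66-fold). Monocytes were high for Ly6C (4.31-fold; Ly6c2 6.76-fold), as were Immature TAM-2 (3.69-fold). Mono/TAM Hypoxic had CD31 at 2.21-fold (Pecam1 3.35-fold) and CD274 at 1.96-fold (RNA 4.72-fold), Mono/TAM IFN Ly6A-Ly6E at 2.66-fold, TAM-2 CD14 at 1.69-fold and Immature TAM-3 Ly6C at 1.90-fold. Single cells with very many tags set some values. Tim4 in Immature TAM-3 (157-fold) came from 1 cell with 22497 of 24255 UMIs, and its log2 ratio was -0.62 without the top 0.1% of cells. CD39 in LLC TAM Hypoxic (3.64-fold; Entpd1 1.45-fold) was at 1.41-fold without those cells. Ly6C in Immature TAM-3 had 7697 of its 26875 UMIs in 1 cell and was at 1.42-fold without the top cells, within the 1.5-fold bound. Scaling also moved sizes, so that the log2 ratio of FRB in TAM-4, 2.54, was 3.06 by centred log ratios, and that of Ly6C in Monocytes, 2.11, was 0.999 in antibody UMIs per cell. In natural log units, the centred log ratio of CD163 in TAM-4 was only 0.304 above the rest, against 2.12 for FRB.

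**Figure D4:**
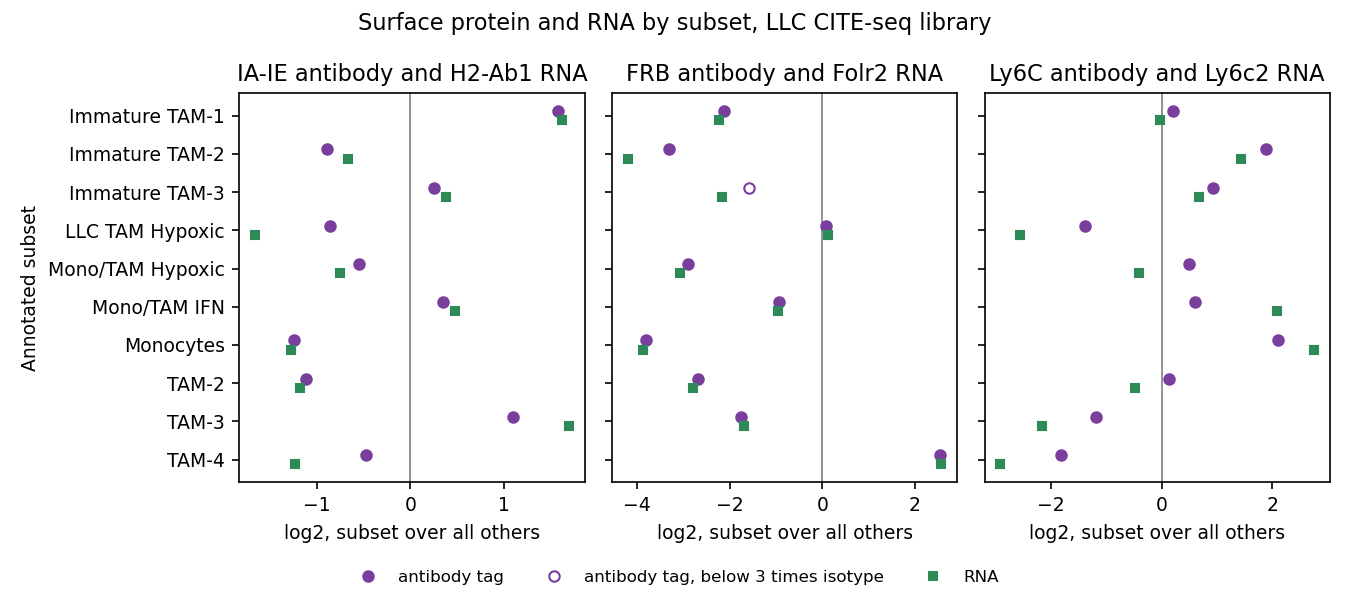
log2 ratio of a subset over all other subsets in the CITE-seq LLC library, for an antibody tag (circles, open where below 3 times the isotype control) and its RNA (squares). FRB in TAM-4 stands at 2.54.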

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

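The 2 tests of the regulatory T cell cluster were written before their values were seen, and no test was added afterwards in this part. Cells of B16 named Tregs-2 in the joint annotation drew attention because another deposited annotation, made from the B16 library alone, named them otherwise. Of the 165 Tregs-2 cells of B16, 140 were also in the other table, where all 140 were called macrophage, monocyte or dendritic cell, 0 were called regulatory T cell, and 25 were absent.

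Tregs-2 carried Foxp3, the gene that defines regulatory T cells, together with phagocyte RNA. Free phagocyte RNA in the droplets as the whole source is argued against, because C1qa was 11.3-fold higher in Tregs-2 than in Tregs-1 of the same library. Doublets of a regulatory T cell with a phagocyte or dendritic cell have the values they need, with 0 genes at least 1.5-fold above every other cluster, a median of 14689 UMIs per cell against 4475 in Tregs-1 and 10368 in the phagocytes and dendritic cells, and 54.5% of the cells among the 6% with the highest doublet scores. By random pairing, 7.66% of pairs would be of this kind, so that 31.3% of the library would have to be doublets to give the cluster its size, and cells that stuck together before loading remain open. No biological explanation was tested, and the Tregs-2 shares of the report hold only under the joint annotation.

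Pmel, a melanocyte gene of the B16 tumour cells, gave a signal outside the compared values, at 4.13 CPM (3.26-5.16) in CD8 T cells of B16, 8.26 CPM in monocytes and macrophages and 24.8 CPM in neutrophils, while Pmel is at 0 in the whole LLC library, a value that filtering of genes before joining also gives, so no contrast with LLC is drawn.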

How the results depend on the processing

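Chosen after seeing the data were the alternatives without the 6% highest doublet scores, with the B16 annotation, with genes at 0 in a library kept and without the 0.1% of cells with most antibody UMIs. Of 3628 recomputed values, 3226 stayed within their interval, 396 moved and 6 reversed. For gene lists the interval is that of the median over member genes, such as -2.29 to -0.51 for MHC class II in monocytes and macrophages. A large move can stay within such an interval, so the tally is not a measure of robustness. Leaving out Scrublet calls, keeping cells with at least 1000 UMIs, requiring at least 100 UMIs, keeping genes at 0 in a library and changing the total moved none. Some of these could hardly move a value. Scrublet called at most 5 cells in a library, and a minimum of UMIs or the kept genes leave the ratio of a single gene unchanged. Median-of-ratios scaling moved 5 of 233 values within classes, the 6% highest doublet scores 25 of 227 with 2 reversed, the mean over cells 34 of 226 and thinning 49 of 207. In the monocyte and macrophage table equal weight per subset moved 24 of 39 with 1 reversed and the CITE-seq LLC library 20 of 39. For antibodies CLR moved 28 of 31 with 1 reversed, UMIs per cell 28 of 31 and leaving out the top cells 9 of 31 with 1 reversed. With 1 library per group, no replicate could be left out, and the cause of each move below was not tested unless stated. No paired analysis was possible because each group is 1 library.

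Among phagocytes and dendritic cells, with neutrophils left out, the LLC over B16 share ratios were 0.0828 for cDC1, 0.600 for cDC2, 0.179 for migDC and 1.06 for monocytes and macrophages, by construction of the denominator. With the B16 annotation they were 0.760 for cDC2 and 1.64 for monocytes and macrophages. Thinned to 2000 UMIs, Cd40 in migDC over monocytes and macrophages was 6.65 in LLC and 4.30 in B16, and in B16 cDC2 gave 2.24 and cDC1 0.557. Cd40 in B16 over LLC was then 3.18 in monocytes and macrophages and 4.22 in cDC2, and 2.74 in monocytes and macrophages as the mean over cells.

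Without the 6% highest doublet scores the neutrophil RNA median in naive T cells was -0.041 and Ccl1 there -1.69 (log2). With at least 1 UMI the T cell exhaustion median in neutrophils was -1.68 in place of 0.35. In the monocyte and macrophage table the interferon response median was -1.20 with the CITE-seq LLC library and -0.45 with equal weight per subset, where Cxcl9 was 0.84.

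For antibodies (log2), Tim4 in Immature TAM-3 was -0.18 by CLR and -0.62 without the top cells, of which 1 cell held most of its UMIs. Ly6C in Monocytes was 1.56 by CLR, 0.999 as UMIs per cell and 2.16 without the top cells. IA-IE in TAM-3 was 1.23 by CLR, 0.79 as UMIs per cell and 1.12 without the top cells. FRB in TAM-4 was 3.06 by CLR and 3.30 as UMIs per cell. Few cells limit cDC1 (35) and CD8 T cells (15) of LLC, and low depth limits its neutrophils, at a median of 1492 UMIs.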

Other observations

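All tests of the genes near F11r and of free neutrophil RNA were chosen after the result was seen, whereas the doublet test of neutrophil-like monocytes was written before. The genes of this part were chosen after their values were seen, apart from members of the fixed lists.

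The 2 LLC libraries differed in macrophage programme too. Compared with the CITE-seq LLC library, the first LLC library had a median log2 ratio of 0.49 for inflammatory genes, 0.39 for classical monocyte genes, 0.39 for dissociation stress genes and 0.26 for hypoxia and glycolysis genes. MHC class II genes were lower in it for 8 of 11 and interferon response genes for 9 of 21. Red cell genes were higher for 4 of 4 (median 4.59). These libraries differ in mouse strain, protocol and pool of mice at once, so none of these factors was singled out.

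RNA typical of the tumour cells was seen in cells annotated as immune, and its source was not tested. The melanocyte genes Dct and Mlana were at 16.2 and 7.84 CPM in monocytes and macrophages of B16 and at 6.16 and 3.54 CPM in its CD8 T cells. The keratin genes Krt8 and Krt18 were at 1.70 and 2.35 CPM in monocytes and macrophages of LLC and at 0 in the whole B16 library, where genes look filtered before joining. The adhesion gene Cdh1 was at 11.6 CPM in LLC and 2.15 CPM in B16 monocytes and macrophages. In naive T cells it was alike, at 6.26 CPM (3 UMIs) in LLC and 6.61 CPM in B16. Epcam of the same list went the other way, at 0 in the whole LLC library and 6.28 CPM in naive T cells of B16. Under the annotation of B16 alone, CD8 T cells were 8.77% and proliferating CD8 T cells 7.78% of that library, cDC1 1.70%, cDC2 3.17% and migDC 2.30%.

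Genes around F11r on chromosome 1 differed between the first LLC library and both C57BL/6J libraries in monocytes and macrophages. Ifi202b stood at 165, 0 and 0 CPM in LLC, CITE-seq LLC and B16, Fcrla at 36.1, 1.1 and 1.25 CPM, Ifi206 at 0, 19.2 and 50.4 CPM and Ifi213 at 0, 23.0 and 50.3 CPM. Counting genes at 0 in a whole library, which the report leaves out, 13 genes within 10 Mb had a 95% interval past 4-fold between the 2 LLC libraries. That is past the bound of 5 set against tumour model alone. The count includes genes at 0 in a whole LLC library, a value that filtering of genes before joining also gives. Among them are Vangl2, at 81, 0 and 14 UMIs in LLC, CITE-seq LLC and B16, and Rbm8a2, at 82, 0 and 29. The count of 13 therefore does not decide on tumour model alone. Interferon level is argued against by a list median of only -0.56 between the LLC libraries while, of the 11 genes apart from both other libraries, 3 were higher and 8 lower. A chromosome segment of another strain carried along with the floxed F11r stays open, because genes at least 4-fold apart lay in the window 5.95 times as often as all genes, between the bounds of 3 and 10 set for it. Without genes at 0 in a library that value was 34.1 (4 of 10 genes, 1 higher and 3 lower), which the segment needs, but only 4 genes in the window were then apart between the LLC libraries (Ifi208, at -2.13 log2, had an interval reaching below 4-fold), between the bounds of 3 and 5 set for the tumour model, though each of the 4 was that far apart within the same model.

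Neutrophil-like monocytes of LLC (890 cells) carried 78.1 UMIs per cell of the neutrophil gene S100a8, against 76.3 in neutrophils and 6.87 in B cells, with a median of 7754 UMIs per cell. As UMIs per cell, S100a8 was 11.4-fold above the highest class other than neutrophils, among classes with at least 50 LLC cells. That argues against free neutrophil RNA as the whole source. By CPM, against the highest of NK, naive T and B cells, the value was 3.47-fold, and on that scale free RNA cannot be told apart from RNA of the cells, since deeper cells dilute it. Doublets of a neutrophil with a monocyte or macrophage have the values they need, with 0 genes at least 1.5-fold above every other cluster and 39.8% of the cells among the 6% with the highest doublet scores, although Imm TAM-4 also had 0 such genes. By random pairing 32.2% of the library would have to be doublets, and no biological explanation was tested.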
